A study of Mus musculus with 4 samples.

How the data were processed

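Poly(A) RNA of the mouse pancreatic cancer line Ink4a was sequenced in 4 libraries, 2 from cells given 5 nM all-trans-retinoic acid (ATRA) for 16 h and 2 from cells given DMSO. Before treatment, the cells had spent 16 h in medium with 10% dialyzed serum, per the labels. RNA was purified on RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, per the labels. Base calls were converted with bcl2fastq 2.20.0, and STAR 2.7.9a, Subread 2.0.1 with featureCounts and the genome build GRCm39 were used, per the submitters' processing notes. The gene annotation, the strand setting of the counting and any filter are not given in the sources used here.

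The authors deposited a table of whole-number counts per gene, with no normalization, and the 4 columns were matched to samples by name. A second deposited table holds a signal per gene, the count divided by 1 size factor per library; per the file name these are DESeq2 normalized counts. Dividing the counts by these values gave size factors of 0.931 to 1.12, constant within each library to a relative deviation of 5e-15. The counts were used for the main test and the normalized values for an alternative.

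Totals were 28035904 to 33860825 counts per library. A floor of 3 counts corresponds to 0.0886 to 0.107 CPM per library, and intervals and floors cover counting error only. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 13372 genes holding at least 99.9% of the counts of each library. Counts were scaled by TMM factors of 0.996 to 1.00. ATRA was compared with DMSO by the quasi-likelihood F-test (robust fit) of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.0175. CPM values use the TMM-scaled totals, except floors and the comparison of blood-cell-type genes with immune markers, which use unscaled totals.

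The gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except a fixed coefficient of variation and the gene family tests under other settings. The 31 lists cover direct retinoic acid targets, retinoid receptors and binding proteins, retinoid metabolism enzymes, netrins and their receptors, other axon guidance genes, Hox clusters, epithelial, mesenchymal, acinar, ductal, endocrine, stellate cell or fibroblast, immune and endothelial genes, G1/S, G2/M, MAPK output, immediate early, TGF-beta, Wnt, Notch, YAP, interferon, NF-kB, p53, cholesterol, hypoxia and glycolysis, unfolded protein response, extracellular matrix protease, mitochondrial and histone genes. Some lists share members. The 26 lists with at least 5 tested members were compared with all other tested genes by limma 3.58.1 camera on voom values, with a preset correlation of 0.01 between genes. Camera was repeated with the correlation estimated per list, under which none of the 15 list calls held. With 4 libraries that version has few residual degrees of freedom, so hardly any list can pass it. Its adjusted p does not decide whether a list moved. Fry tested whether the genes of a list moved, on balance, one way, without comparing the list with other genes. The genes named were, first, the 10 with the largest increase and the 10 with the largest decrease among called genes with a mean log2 CPM of at least 1 whose libraries did not overlap between groups, leaving out unnamed gene models. Second came a fixed set around netrin, retinoid signalling and the genotype, and last up to 4 members of each list with the smallest adjusted p. Other genes were chosen after their values were seen, as said beside them in the report and at the top of the closing section.

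The tools were tested on simulated counts with the real means, library sizes and estimated dispersion trend, in which 200 genes were changed. This test was first run after the real data had been fitted. Spread of single genes around the trend and further spread between cultures were not simulated, so its shares do not give the false calls in the real data. For ATRA against DMSO, edgeR recovered 57% of the genes changed 1.25-fold and 89% of those changed 2-fold over 13224 genes, and 2.67% of its calls were false. DESeq2 1.42.0 recovered 43% and 83% over 13372 genes with 0% false calls, and limma-voom 55% and 88%.

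Alternatives were RLE factors, library size alone, no filter beyond 1 count, a filter of at least 1 CPM in 2 libraries, DESeq2, limma-voom, limma-trend on log2 of the deposited normalized count plus 1, the replicate number as a block, each library left out in turn, a non-robust fit, an adjusted p under 0.01 and a 2-fold minimum. A coefficient of variation of 0.1 for every gene was added after the data had been seen. With 1 library left out, the lone library was assumed to vary like the other group.

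Gene neighbours, overlaps, transcript lengths and GC contents were taken by gene symbol from the GENCODE M21 annotation of GRCm38, which matched 12928 of the tested genes. It is another build than the authors', so no coordinates are given. Counts of genes that overlap on the same strand, of close paralogs, and of genes with an antisense partner (the strand setting being unknown) are uncertain. Named genes with a protein-coding partner on the other strand include Tgm2, Rarb, Kras, Cyp51, Ccnd1, Ccne2, Cdc45, Crim1, Fosl1, Timp1, Timp3, Eng, Rbpjl, Stab1, Adgre5, Mmp24 and Rarres2. Dusp1, Junb and Esrp2 have such partners too, at mean levels of 342 CPM (Ergic1), 199 CPM (Prdx2) and 165 CPM (Nfatc3). In the table, 6 consecutive mitochondrial mRNAs from mt-Co2 to mt-Nd4l held 2 counts in all, while the neighbouring mt-Co1 held 426445 and mt-Nd4 85307, so a 0 in this table can also be reads that were not counted.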

Results

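Gene expression was measured by RNA sequencing in Ink4a cells, a mouse pancreatic ductal adenocarcinoma line from mice with an activated Kras allele and deletion of the Ink4a/Arf locus in the pancreatic lineage. The cells received either the solvent DMSO or 5 nM all-trans-retinoic acid (ATRA), the active metabolite of vitamin A, for 16 h. Each group had 2 libraries, numbered 2 and 3. The series holds no library with a lower number, and the sources used here do not say why. Total gene counts were 29948269 and 28035904 in the ATRA libraries and 29588975 and 33860825 in the DMSO libraries. Of 56832 genes in the table, 32990 had 0 counts in all 4 libraries and 13372 passed the low-count filter. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these 4 samples, which may be technical. Levels below are mean scaled counts (CPM) ± SD over n = 2 libraries per group, and log2 fold changes (ATRA over DMSO) are given with the SE of the fit.

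The targeted locus and the lineage driver were examined first. Cdkn2a, the gene of the deleted Ink4a/Arf locus, had 0 counts in all 4 libraries. A count of 0 allows at most 0.0886 to 0.107 CPM per library (3 counts, counting error only). Ptf1a, the acinar transcription factor whose locus drove Cre, also had 0 counts in all 4 libraries. Kras stood at 109 ± 1.02 CPM with ATRA and 116 ± 1.38 CPM with DMSO (log2 fold change -0.09 ± 0.03, adjusted p = 0.0307). That call ended without ATRA replicate 2 (adjusted p = 0.179), ATRA replicate 3 (0.0772) or DMSO replicate 3 (0.141), and in DESeq2 (0.284). The libraries separated by treatment. Correlations of log2 CPM across genes, which are not independent replicates, were 0.996 between the ATRA libraries and 0.997 between the DMSO libraries, against 0.989 to 0.990 between groups. The first principal component held 72.9% of the variance and separated ATRA from DMSO. The libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.59 for ATRA and 2.30 for DMSO.

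The comparison of ATRA with DMSO asked which genes the retinoid changed in these cells, in a study whose title concerns netrin-1. Among the largest increases were genes of the retinoic acid response. Cyp26b1, which degrades retinoic acid, rose most of the genes named by rule. Its level went from 0.323 ± 0.171 CPM (6 and 15 counts with DMSO) to 30.4 ± 0.196 CPM, a fitted 90.7-fold difference. Dhrs3, which reduces retinaldehyde to retinol, was 21.1-fold higher, and Stra6, a membrane receptor for retinol uptake, was 13.7-fold higher. Ntn1, which encodes netrin-1, rose from 61.6 ± 3.45 to 94.1 ± 0.278 CPM (log2 fold change 0.61 ± 0.04, adjusted p = 3.6e-16). Krt19, Krt18, Krt8, Krt7 and Spp1 rose, while Krt14, Vim and Acta2 fell. The epithelial list had 6 of 12 tested members higher and 3 lower. The mesenchymal list, which includes Spp1, had 5 of 20 higher and 7 lower. Of the immediate early genes 11 of 18 tested fell and 2 rose, and of the cholesterol synthesis genes 13 of 23 fell and 2 rose, with an adjusted p of 0.419 for each list with an estimated correlation. In edgeR's quasi-likelihood test, 2192 genes were higher and 2005 lower with ATRA at a Benjamini-Hochberg adjusted p under 0.05. Together they made up 31.4% of all tested genes, so a list with about that share of called members does not stand out by its count.

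Most of these differences were small. The median absolute log2 fold change of the called genes was 0.22, and 2808 of them (66.9%) changed by less than 1.25-fold. Among called genes with at least a 2-fold difference, 303 were higher and 30 lower. At 4-fold, 90 were higher and 3 lower. The ATRA and DMSO libraries did not overlap for 62.9% of tested genes, where chance gives 33.3% for 2 libraries against 2. DESeq2 called 1088 genes higher and 968 lower.

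**Figure D1:**
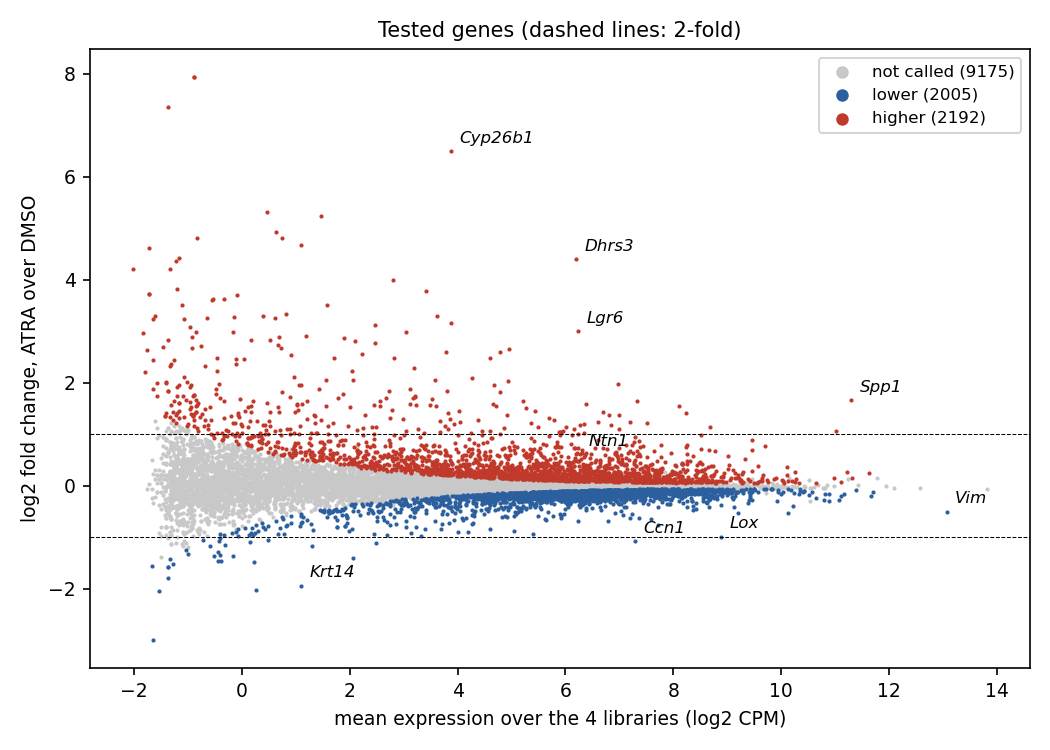
Log2 fold change of ATRA over DMSO (y axis) against mean log2 CPM over the 4 libraries (x axis) for 13372 tested genes, with 2192 called higher in red, 2005 called lower in blue and the others in grey. Changes beyond the dashed 2-fold lines were mostly increases (303 against 30), and the fitted folds of genes with 0 DMSO counts are no bounds.

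The 10 largest increases named by rule were, after Cyp26b1, in Csn3, a milk casein gene (37.8-fold), Dhrs3, Eln (elastin, 15.9-fold), Stra6, the bicarbonate transporter gene Slc4a4 (11.4-fold), Usp43 (9.84-fold), the glycosyltransferase gene Mgat3 (8.95-fold), Oasl1 (8.75-fold) and Lgr6 (8.04-fold). Csn3 had 155 and 164 counts with ATRA against 3 and 6 with DMSO. Lgr6, an R-spondin receptor, reached 137 ± 0.981 CPM from 17.0 ± 0.135 CPM. The 10 largest decreases were smaller. Krt14, a basal keratin, fell by 1.94 on the log2 scale, Siglecg by 1.40, Klhl22 by 1.18, and Hecw1 fell as well. The matricellular gene Ccn1 had a log2 fold change of -1.08 ± 0.16, from 210 ± 10.1 to 99.2 ± 16.6 CPM, with an adjusted p of 0.0484. Its adjusted p was 0.300 without DMSO replicate 2, 0.326 without DMSO replicate 3, 0.186 with the replicate block and 0.111 without the low-count filter. Lox, which crosslinks collagen, fell from 631 ± 24.8 to 318 ± 7.56 CPM. Col6a3, Atp2b4, Plk2 and Dusp8 had log2 fold changes of -0.97, -0.96, -0.94 and -0.93.

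Of 18 tested direct retinoic acid targets, 17 rose, and 18 when adjusted over the list alone. The list's median log2 fold change was 1.42, and the overlap with the higher genes had a one-sided Fisher's exact p of 6.44e-13. In limma's camera test the list moved up relative to other genes (adjusted p = 8.22e-19, or adjusted p = 0.257 with an estimated correlation). Tgm2, a transglutaminase, rose from 87.6 ± 0.0853 to 208 ± 3.88 CPM (it overlaps Rprd1b on the other strand, so its count is uncertain), and Nrip1, a corepressor of nuclear receptors, from 41.8 ± 0.854 to 126 ± 0.786 CPM. Cyp26a1 had 11 and 10 counts with ATRA and 0 and 1 with DMSO, a ratio of pooled counts of 23.0 with a 95% counting interval of 3.70 to 950. Hoxa1 did not pass (log2 fold change 0.45 ± 0.20, adjusted p = 0.0964), but passed without DMSO replicate 2 (0.0133).

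Among 17 tested retinoid receptors and binding proteins, 8 rose, the same number adjusted over the list alone (camera adjusted p = 0.00158, or adjusted p = 0.378 with an estimated correlation). Rarg, a retinoic acid receptor, had a log2 fold change of 0.61, and Crabp2, which carries retinoic acid to the nucleus, rose from 50.1 ± 0.828 to 87.8 ± 0.265 CPM. Rarb had 26 and 37 counts against 0 and 7 (log2 fold change 3.26 ± 0.53, adjusted p = 9.4e-06, 0.231 in DESeq2), and it overlaps Top2b on the other strand. Rara and Rbp1 rose slightly (log2 fold changes 0.13 ± 0.04 and 0.23 ± 0.06, adjusted p = 0.0176 and 0.00508). Rara did not pass without ATRA replicate 2 (0.0812), without DMSO replicate 2 (0.336) or in DESeq2 (0.313), nor Rbp1 without DMSO replicate 3 (0.118) or in DESeq2 (0.207). Rxra did not pass (log2 fold change -0.08 ± 0.04, adjusted p = 0.0938), but passed as lower without DMSO replicate 2 (0.0360). Of 15 tested retinoid metabolism enzymes, 6 rose and 2 fell, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0257, or adjusted p = 0.378 with an estimated correlation). The retinol dehydrogenase gene Rdh10 fell from 84.8 ± 0.475 to 69.9 ± 0.987 CPM. Akr1b8, an aldo-keto reductase, rose from 62.2 ± 1.84 to 86.4 ± 1.95 CPM. Aldh1a3, which makes retinoic acid, had 1 count in total.

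**Figure D2:**
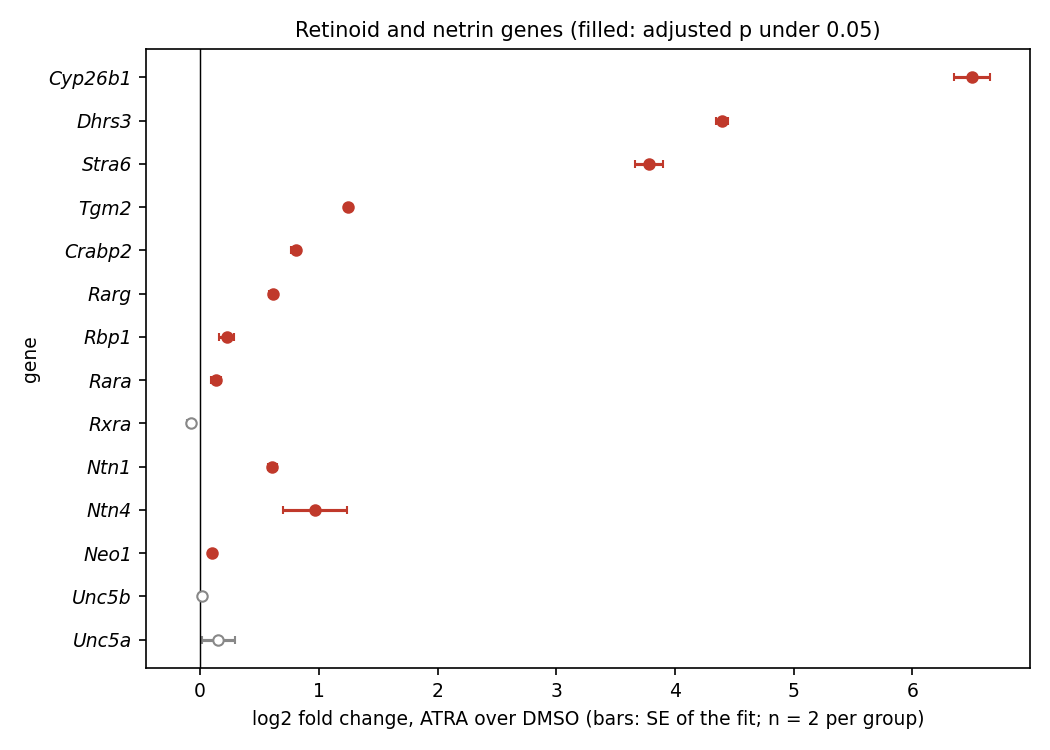
Log2 fold change of ATRA over DMSO (x axis; bars are the SE of the fit, 2 libraries per group) for retinoid and netrin genes (y axis), with filled points for an adjusted p under 0.05. Cyp26b1 stood at 6.50, Ntn1 at 0.61, and Rxra, Unc5b and Unc5a (open points) did not pass.

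Of 6 tested netrins and netrin receptors, 3 rose, the same number adjusted over the list alone: Ntn1, Ntn4 and Neo1. The list's camera adjusted p was 0.0402, or adjusted p = 0.378 with an estimated correlation. It was 0.0599 without ATRA replicate 2, 0.104 without DMSO replicate 2 and 0.0938 without DMSO replicate 3. Ntn4, another secreted netrin, went from 0.808 ± 0.0965 to 1.57 ± 0.00493 CPM (adjusted p = 0.00483; 0.0617 without DMSO replicate 3 and 0.198 in DESeq2). The receptor gene Neo1 had a log2 fold change of 0.10 ± 0.03 (adjusted p = 0.00291, 0.153 in DESeq2). Unc5b, the most highly expressed netrin receptor tested, stood at 297 ± 7.12 and 294 ± 7.01 CPM (adjusted p = 0.767). Unc5a was at 4.36 ± 0.00614 and 3.90 ± 0.376 CPM (adjusted p = 0.461). Dcc, the classical netrin receptor, had 0 counts in all 4 libraries. Among 29 other axon guidance ligands and receptors, 16 rose and 4 fell, and 18 and 5 when adjusted over the list alone (camera adjusted p = 0.00158, or adjusted p = 0.385 with an estimated correlation). Sema7a had a log2 fold change of 0.62, and the semaphorin receptor gene Nrp1 rose from 56.7 ± 0.908 to 78.3 ± 1.51 CPM. Sema3a and Sema3f had log2 fold changes of 0.25 and 0.38. Epha4 and Slit2, named after their values were seen, had log2 fold changes of -0.74 and -0.41.

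Of 22 tested Hox cluster genes, 6 rose and 1 fell, and 7 and 1 when adjusted over the list alone (camera adjusted p = 0.0697, or 0.0390 without ATRA replicate 2). Hoxa3 rose from 4.32 ± 0.0403 to 14.1 ± 0.786 CPM and Hoxa5 from 3.77 ± 0.725 to 13.9 ± 1.02 CPM. These genes and Hoxa6 (log2 fold change 1.07, adjusted p = 0.107 in DESeq2) overlap on the same strand in the annotation, so their counts are uncertain. Hoxb9 had a log2 fold change of -0.39 ± 0.09 (adjusted p = 0.000872, 0.0895 in DESeq2).

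Of 12 tested epithelial transcription factors and junction genes, 6 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0239, or adjusted p = 0.378 with an estimated correlation). In DESeq2, 4 rose and the 3 lower calls were lost (2 had an unadjusted p under 0.05). The list median was 0.02. The members that fell, named after their values were seen, were Esrp2, Pkp1 and Klf4 (log2 fold changes -0.47, -0.46 and -0.12). Their adjusted p in DESeq2 was 0.168, 0.0605 and 0.291. Esrp2 overlaps Nfatc3 on the other strand, so its count is uncertain. Klf4 also lost its call without ATRA replicate 2 (0.0848), ATRA replicate 3 (0.105) or DMSO replicate 3 (0.106). The untested members of this list, among them Cdh1 and Epcam, had mean levels of at most 0.251 CPM. Most members of the list that rose were keratins. Krt19, a ductal keratin, rose from 18.4 ± 1.40 to 57.4 ± 2.10 CPM, Krt7 from 0.863 ± 0.0767 to 3.37 ± 0.0244 CPM, Krt18 from 414 ± 4.09 to 622 ± 3.27 CPM, and Krt8 had a log2 fold change of 0.39. Elf3, an epithelial ETS transcription factor, had 14 and 10 counts with ATRA and 1 and 3 with DMSO (log2 fold change 2.64 ± 0.68, adjusted p = 0.00246, or 0.0666 without DMSO replicate 2). Of 9 tested ductal and progenitor markers, 5 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00506, or adjusted p = 0.378 with an estimated correlation). Spp1, which encodes osteopontin, rose from 1207 ± 41.5 to 3829 ± 1.64 CPM and the pancreatic homeobox gene Pdx1 had a log2 fold change of 0.29, while Foxa2 fell from 17.4 ± 0.114 to 13.2 ± 0.744 CPM.

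Of 20 tested mesenchymal and EMT genes, 5 rose and 7 fell, and 5 and 8 when adjusted over the list alone (camera adjusted p = 0.359). The list's median log2 fold change was -0.03, its mean 0.08, and camera gave a downward and fry an upward sign. Vim, the intermediate filament vimentin, fell from 10098 ± 70.6 to 7123 ± 36.2 CPM and Acta2, smooth muscle actin, from 200 ± 6.63 to 130 ± 2.87 CPM. Loxl2, a collagen crosslinking enzyme, rose from 12.3 ± 0.322 to 50.1 ± 1.73 CPM. Of 11 tested stellate cell and fibroblast markers, 4 rose and 3 fell, and 5 and 5 when adjusted over the list alone (camera adjusted p = 0.949, with a median of -0.03, a mean of 0.01 and a downward sign in camera but an upward sign in fry). Pdgfra rose from 95.8 ± 0.126 to 138 ± 1.05 CPM, Col3a1 had a log2 fold change of 0.23 and Col1a2 of -0.21. Of 21 tested extracellular matrix proteases and inhibitors, 10 rose and 8 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.581). Timp1, a protease inhibitor, fell from 336 ± 4.82 to 275 ± 3.15 CPM and Timp3 rose from 196 ± 1.26 to 250 ± 7.45 CPM. Mmp3, chosen after its values were seen, had 20 and 19 counts with ATRA and 0 in both DMSO libraries. Its ATRA level was 14.2-fold above a floor of 3 counts over the DMSO group. That ratio leaves out the counting error of the ATRA counts, so it is not a lower limit.

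Few markers of other cell types passed the low-count filter. Of 2 tested acinar markers, Rbpjl stood at 0.451 ± 0.0685 and 0.310 ± 0.105 CPM (adjusted p = 0.455) and Cela1 at 2.05 ± 0.229 and 2.29 ± 0.567 CPM (adjusted p = 0.654). Of 2 tested endocrine markers, 1 rose, Pax6 (24.1 ± 0.0103 to 35.6 ± 2.19 CPM), and Mafa had an adjusted p of 0.306. Of 3 tested immune cell markers, 1 rose: Cd14 went from 23.1 ± 0.795 to 39.2 ± 1.20 CPM, while Lyz2 and Cd68 had adjusted p of 0.156 and 0.999. The endothelial marker Flt1 stood at 264 ± 3.81 and 257 ± 2.26 CPM (adjusted p = 0.299). The other 3 tested endothelial markers had at most 2.11 CPM, with adjusted p of 0.380 (Cdh5), 0.417 (Eng) and 0.613 (Esam). The counts for these 4 lists were the same adjusted over the list alone. The untested members of the acinar, endocrine, immune and endothelial lists had mean levels of at most 0.139, 0.149, 0.212 and 0.0662 CPM.

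Of 18 tested immediate early genes, which respond within minutes to growth factors and stress, 11 fell and 2 rose, and 13 and 3 when adjusted over the list alone (camera adjusted p = 8.24e-05, or adjusted p = 0.419 with an estimated correlation). Myc fell from 142 ± 0.893 to 98.0 ± 1.26 CPM, Jun from 159 ± 6.96 to 107 ± 6.59 CPM and Klf6 from 159 ± 2.29 to 119 ± 5.88 CPM. The members that rose, named after their values were seen, were Junb and Dusp1 (log2 fold changes 0.28 and 0.31). They overlap Prdx2 and Ergic1 on the other strand, so their counts are uncertain. Dusp1 lost its call in DESeq2 (adjusted p = 0.383) and without ATRA replicate 2 (0.109), ATRA replicate 3 (0.0663) or DMSO replicate 2 (0.139). Of 11 tested Hippo YAP target genes, 8 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00139, or adjusted p = 0.498 with an estimated correlation). Axl, a receptor tyrosine kinase, Ptpn14 and Tead1 had log2 fold changes of -0.16, -0.18 and -0.14, and Crim1 of 0.18. Of 17 tested MAPK output genes, 5 rose and 4 fell, and 7 and 4 when adjusted over the list alone (camera adjusted p = 0.869, with a median of 0.03, a mean of -0.02 and an upward sign). The ERK phosphatase gene Dusp6 fell from 179 ± 2.51 to 122 ± 2.94 CPM, Fosl1 had a log2 fold change of -0.35, and Spred2 and Ccnd1 of 0.43 and 0.27.

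Of 15 tested TGF-beta target genes, 6 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.018, or adjusted p = 0.378 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, rose from 40.9 ± 1.24 to 89.6 ± 2.21 CPM and Ltbp2 from 95.9 ± 4.40 to 151 ± 3.61 CPM. Pmepa1 and Skil had log2 fold changes of 0.48 and 0.39. Serpine1, a protease inhibitor gene named after its values were seen, fell from 91.9 ± 5.81 to 57.2 ± 4.82 CPM. The ligand gene Tgfb1 had a log2 fold change of 0.19 ± 0.04 (adjusted p = 5.75e-05). Tgfb2 did not pass (0.37 ± 0.15, adjusted p = 0.0508), but passed without DMSO replicate 3 (0.0164), with the replicate block (0.0392) and under a stricter filter (0.0488). Of 6 tested Wnt target genes, 3 rose, the same number adjusted over the list alone (camera adjusted p = 0.0856, or 0.0461 without ATRA replicate 3, and 0.0459 in fry). The stem cell receptor gene Lgr5 rose from 1.44 ± 0.244 to 9.84 ± 1.21 CPM and Axin2, a feedback inhibitor of the pathway, from 1.97 ± 0.554 to 4.04 ± 0.444 CPM. The third, Tcf7, had a log2 fold change of 0.52 (adjusted p = 0.0551 in DESeq2). Of 11 tested Notch pathway genes, 3 rose and 3 fell, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.803). Hes6 had a log2 fold change of 0.61 and the ligand gene Jag1 of -0.48. The receptor gene Notch1 had a log2 fold change of -0.17 and lost its call in DESeq2 (adjusted p = 0.0926) and without ATRA replicate 2 (0.0552).

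Of 15 tested interferon response genes, 5 rose and 1 fell, the same numbers adjusted over the list alone. The gene that fell, Ifit2 (log2 fold change -0.18, named after its values were seen), had no call in DESeq2 (adjusted p = 0.330), where 4 members rose, or without ATRA replicate 2 (0.0969), ATRA replicate 3 (0.0893) or DMSO replicate 2 (0.199). The camera adjusted p was 0.0173, or adjusted p = 0.378 with an estimated correlation, and 0.0877 and 0.109 without DMSO replicates 2 and 3. The paralogs Oasl1 and Oasl2, which can share reads, rose from 1.17 ± 0.0628 to 10.2 ± 0.533 CPM and from 0.0653 ± 0.0506 to 0.764 ± 0.180 CPM. The transcription factor gene Irf1 rose from 16.8 ± 0.476 to 30.2 ± 0.128 CPM. Of 12 tested NF-kB targets and chemokines, 3 rose and 4 fell, and 4 and 4 when adjusted over the list alone (camera adjusted p = 0.581). Vcam1, an adhesion molecule, and Tnfaip3, an NF-kB inhibitor, had log2 fold changes of 0.87 and 1.28. Csf1 and Ptgs2 had log2 fold changes of -0.42 and -0.64. Of 19 tested p53 target genes, 3 rose and 6 fell, and 4 and 7 when adjusted over the list alone (camera adjusted p = 0.0856). Sesn1 had a log2 fold change of 0.57 and the cell cycle inhibitor gene Cdkn1a of -0.29.

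Of 23 tested G2/M genes, 16 rose, and 19 when adjusted over the list alone (camera adjusted p = 8.24e-05, or adjusted p = 0.378 with an estimated correlation). The changes were small, with a list median of 0.08. Top2a, a topoisomerase of dividing cells, rose from 1028 ± 5.92 to 1189 ± 30.5 CPM and the mitotic cyclin gene Ccnb2 from 138 ± 5.49 to 160 ± 1.19 CPM. Of 24 tested G1/S and DNA replication genes, 6 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.673). DESeq2 passed 0 of these genes as higher (2 at an unadjusted p under 0.05). The cyclin gene Ccne2 fell from 43.7 ± 2.59 to 36.8 ± 0.551 CPM. Cdc45, a replication fork factor, had a log2 fold change of 0.13, without a call in DESeq2 (adjusted p = 0.230) or without ATRA replicate 3 (0.0884). Of 3 tested replication-dependent histone genes, 1 fell, also when adjusted over the list alone: H1f2 had a log2 fold change of -0.26 ± 0.10 (adjusted p = 0.0495, 0.444 in DESeq2, 0.0611 in limma-voom, 0.0537 with the replicate block or without the low-count filter, and 0.0942 to 0.195 with 1 library left out).

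Of 23 tested cholesterol synthesis genes, 13 fell and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00101, or adjusted p = 0.419 with an estimated correlation, and 0.0960 without DMSO replicate 3). Hmgcr, the rate-limiting enzyme, fell from 143 ± 2.96 to 121 ± 1.20 CPM, and Sqle and Cyp51 had log2 fold changes of -0.21 and -0.25. Insig1, which restrains the pathway, rose from 41.7 ± 0.891 to 70.6 ± 3.19 CPM. Of 26 tested hypoxia and glycolysis genes, 10 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0359, or adjusted p = 0.378 with an estimated correlation). The list median was 0.02. Slc2a1, a glucose transporter gene named after its values were seen, had a log2 fold change of -0.19, without a call in DESeq2 (adjusted p = 0.0634) or without DMSO replicate 3 (0.137). Pfkfb4, a regulator of glycolytic flux, had a log2 fold change of 1.05, and Hk2 rose from 54.3 ± 0.0872 to 74.7 ± 3.18 CPM. Of 19 tested unfolded protein response genes, 8 rose and 2 fell, and 8 and 3 when adjusted over the list alone (camera adjusted p = 0.589). The chaperone gene Hspa5 had a log2 fold change of 0.10 and Asns of -0.27. Of 7 tested mitochondrially encoded mRNAs, 2 rose, and 3 when adjusted over the list alone. The camera adjusted p was 0.0107, or adjusted p = 0.568 with an estimated correlation, and 0.331 without ATRA replicate 2. The 2 were mt-Nd1 and mt-Nd2, with log2 fold changes of 0.07 and 0.10, which lost their calls without ATRA replicate 2 (0.351 and 0.0620). The gene mt-Nd5 did not pass (log2 fold change 0.11 ± 0.04, adjusted p = 0.0563), but passed under 7 alternatives, among them the replicate block (0.000107), limma-voom (0.00162) and leaving out ATRA replicate 3 (4.67e-06).

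**Figure D3:**
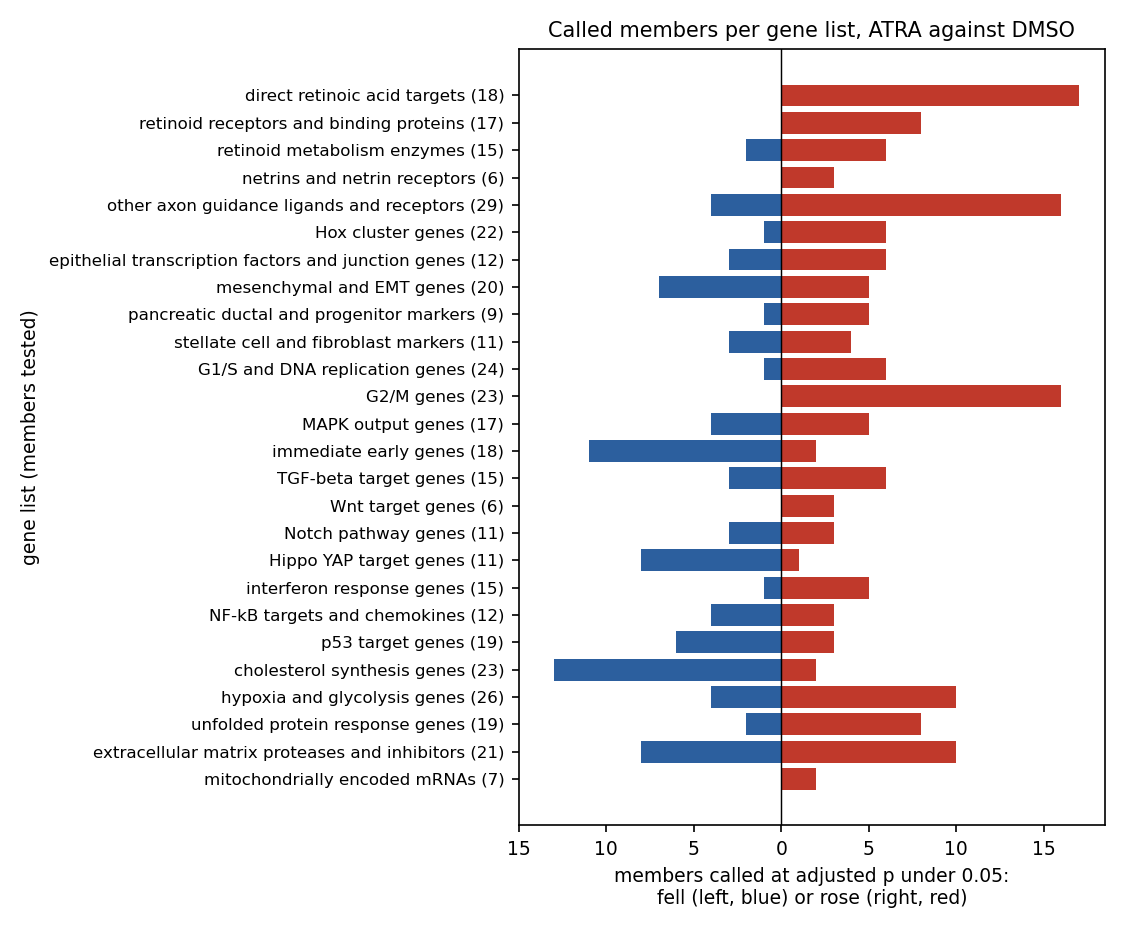
Number of members that rose (red, right) or fell (blue, left) with ATRA at an adjusted p under 0.05 (x axis, counted from 0 in each direction) for the 26 gene lists with at least 5 tested members (y axis, number tested in parentheses). Direct retinoic acid targets had 17 of 18 members higher, and cholesterol synthesis genes had 13 of 23 lower. Of all tested genes, 31.4% were called in either direction.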

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

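The coefficient of variation of 0.1 was chosen after the data had been seen, and the other alternatives in this part beforehand. The counts of 2192 higher and 2005 lower genes stayed within 1.5 times under RLE factors, library size alone, either filter, limma-voom, limma-trend, the non-robust fit and the adjusted p under 0.01, and no setting called a gene in the opposite direction. DESeq2 called 1088 and 968, of which 1088 and 966 were among the main calls; the cause was not tested. With the coefficient of variation set to 0.1 the counts were 633 and 141, and with a minimum of 2-fold 303 and 30, as fewer small changes can pass by construction; the share of higher calls was then 81.8% for the coefficient of 0.1 against 52.2%. Leaving out 1 library gave 1794 to 1956 higher and 1507 to 1792 lower genes, 12 to 16 lists and 13 to 16 called retinoic acid targets.

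Camera with an estimated correlation passed 0 of 26 lists (2 at an unadjusted p under 0.05), against 15 with the preset one and 11 with fry. The estimated version rests on the few residual degrees of freedom that 4 libraries in 2 groups leave, so hardly any list can pass it. It therefore does not decide whether a list moved, and the preset correlation remains an assumption. Retinoic acid targets among the higher genes numbered 11 of 17 in DESeq2 (Fisher's exact p = 6.68e-09). DESeq2 also counted fewer members that rose among receptors and binding proteins (5 against 8), metabolism enzymes (3 against 6), netrins (1 against 3), axon guidance (10 against 16, and 2 against 4 that fell), Hox (2 against 6), mesenchymal (3 against 5), ductal (3 against 5), G2/M (8 against 16), immediate early (1 against 2), Notch (1 against 3), cholesterol (1 against 2) and unfolded protein response genes (2 against 8). Fewer fell among YAP (5 against 8), NF-kB (2 against 4) and cholesterol genes (6 against 13). DESeq2 passed 0 G1/S genes as higher (2 at an unadjusted p under 0.05) against 6 in edgeR. As lower it passed 0 epithelial genes (2 unadjusted) against 3, and 0 Hox (1 unadjusted), interferon and histone genes (0 unadjusted in each) against 1 in each. Fry did not pass 5 lists that camera passed: axon guidance (0.0505), immediate early (0.0547), YAP (0.0937), cholesterol (0.0960) and mitochondrial (0.271). It passed Wnt targets (0.0459), which camera did not (0.0856).

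The replicate numbers are shared between the groups, but deviations of same-numbered libraries correlated at only 0.0379. This correlation shows no clear pairing by number, but cannot exclude that same-numbered libraries were handled together. With the replicate block the counts were 2217 and 1994, with 15 lists and 17 retinoic acid targets. Of 181 named genes with a fit, 37 changed their side of the threshold under at least 1 setting, as did 17 of 26 lists, and no call reversed. Library size alone and RLE factors shifted all genes by a median log2 of -0.00391 and -0.00288.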

Other observations

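The genes named here outside the fixed rule were chosen after their values were seen. The following tests were chosen only after results were seen: the chi-square between libraries of a group, the 5 blood-cell-type genes compared with immune markers, the ratio over all tested immediate early and YAP members with its simulation and its comparison with random lists, the permutations within expression bins, the rise over all immune markers and of each of them, the families under other settings, and the count of pairs of 1 family or overlapping.

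Several single genes known from blood or endothelial cells rose with ATRA. In the fixed lists, which had too few tested members for a list test, 1 of 3 tested immune markers rose and the 4 tested endothelial markers did not pass. Itgb2, a leukocyte integrin subunit, rose from 1.08 ± 0.191 to 7.63 ± 0.255 CPM (mean ± SD, n = 2), Adgre5 from 3.99 ± 0.547 to 24.3 ± 0.923 CPM, Slfn2 from 1.38 ± 0.141 to 8.12 ± 0.893 CPM and Stab1 had a log2 fold change of 2.49. Cd38, an NAD-consuming ectoenzyme listed among the retinoic acid targets, rose 6.32-fold. Rarres2, which encodes chemerin, rose 30.3-fold, with 95 and 78 counts with ATRA against 3 and 3 with DMSO. The chemerin receptor gene Cmklr1 rose 3.26-fold in the same libraries. Thbd (thrombomodulin) was 2.84-fold and Selp (P-selectin) 2.93-fold higher.

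Gene families were compared by the stem of their symbols, 208 in each direction. In a one-sided Fisher's exact test over all 4 libraries, 2 families were enriched among called changes of at least 2-fold: keratins (4 of 10 higher, adjusted p = 0.0203) and matrix metalloproteinases (4 of 13 higher, adjusted p = 0.0327). The keratins were Krt7, Krt13, Krt19 and Krt84, the last without a call in DESeq2 (adjusted p = 0.260), without ATRA replicate 2 (0.0773) or without DMSO replicate 3 (0.188). Without that call the keratin result did not pass either, with adjusted p of 0.0682, 0.0883 and 0.107 in these settings, and the metalloproteinase result did not pass without ATRA replicate 2 (0.161) or DMSO replicate 3 (0.0708). Krt14 fell. The metalloproteinases were Mmp3, Mmp10, Mmp13 and Mmp24, with Mmp10 at 43 and 39 counts against 5 and 2, and Mmp13 at 12 and 22 against 2 and 3. Among tested genes only, Mmp3 lies next to Mmp13 and to Mmp10 in the annotation. In the same sense Krt13 lies next to Krt19 and Krt7 next to Krt84.

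The rise of blood-cell-type genes was set against reads from blood cells in the ATRA libraries. Itgb2, Adgre5, Slfn2, Stab1 and Cmklr1 rose by 8.36 CPM on average. The CPM in this paragraph are pooled counts over unscaled library totals, so they differ slightly from the levels above. The 14 immune markers too low to be tested, among them Ptprc, Tyrobp and C1qa, held 23 counts in the ATRA and 24 in the DMSO libraries, with an upper 95% limit of 0.595 CPM for their sum in ATRA, but such markers are low by selection. Over all 17 markers in the table, tested or not, the summed rise was 16.9 CPM, of which Cd14 made up 16.0 CPM, and Cd14 was the 1 marker whose rise could reach 8.36 CPM (upper 95% limits of at most 1.48 CPM for the others), which argues against blood cells that carry most of these markers. Cells that lack most of them stay open, and no cause was tested for Cd14. Antisense reads also stay open for Stab1 and Adgre5, which overlap Nt5dc2 and Ddx39 on the other strand.

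Genes that rose by at least 2-fold often lay side by side. There were 35 such adjacent pairs among 12906 adjacent pairs of tested genes, against 6.7 on average over 10000 permuted gene orders and 6.8 with genes swapped within 20 expression bins (permutation p = 1e-04 in each, the smallest these permutations can give), which argues against chance placement. Without pairs of 1 symbol family and overlapping genes, 20 pairs were left, against 5.51 and 5.14 on average (permutation p = 1e-04 in each). Pairs recognised as 1 family or as overlapping therefore did not make up the whole excess. For the other 15 pairs, of 1 family or overlapping, reads shared between the genes stay open. Among the 20 they stay open for Sele and Selp, paralogs that the symbol rule left in. They also stay open for pairs with an unnamed gene model, such as Gimap5 with 4833403J16Rik and Caprin2 with Gm7618. The symbols of such models give no family, and overlaps came from another build than the authors'. In the other pairs among the 20, both genes have a name. Examples are Selp with F5, Thbd with Cd93, Stra6 with Islr, and Lgr6 with Ptprv, of which F5 (adjusted p = 0.0638) and Cd93 (0.125) had no call in DESeq2, and Cd93 none without DMSO replicate 2 (0.0928). Neither transcription from shared regulatory regions nor read-through from one gene into the next was tested.

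The fall of immediate early and YAP target genes was set against random differences between dishes, since these genes respond to handling. The 22 called members include Junb, Dusp1 and Crim1, which rose. Over these 22, the size of the difference between groups, in either direction, was a median of 3.448 times the larger replicate difference (bootstrap interval over members 2.85 to 4.49). Called members are picked for such a ratio, but over all 29 tested members it was 3.16 (2.54 to 4.14), with 5 members at a ratio of 1 or less, and a single random state per dish would reach that in 3.08% of simulated sets of 2 and 2 dishes. Both bootstrap intervals resample genes measured in the same 4 libraries, so they do not measure the spread between dishes. The labels do not say that the libraries of a group came from separate dishes. Dish-to-dish differences therefore cannot be told apart from an effect of ATRA by these values. These genes also spread more between replicates than others, at the 99.9th percentile of 10000 expression-matched lists. A difference in handling that followed the groups cannot be excluded from 4 libraries, and the labels name no plate or order.

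Removing a trend with transcript length and GC content per library left 4447 calls against 4159 before, 4007 of them shared, over the 12928 genes with a length. The larger chi-square per degree of freedom between the libraries of a group was 2.303, above the 1 of pure sampling, which does not say whether the spread is between cultures or between library preparations.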
